A study of Homo sapiens with 6 samples.

How the data were processed

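RNA was measured in 6 libraries of Panc1 cells, 3 given DMSO and 3 given BRQ, per the labels. Groups and replicate numbers were taken from the sample titles. Total RNA was extracted with TRIzol and sequenced with standard Illumina library preparation, per the labels' protocols. Selection of poly(A) RNA, strand, read length, aligner and annotation were not given in the sources used here. The submitters' processing notes name fastp, a read trimmer, HTSeq, a counter of reads per gene, and the genome build hg38. The authors deposited one table for the series, with FPKM values per gene and library, an Entrez number and pathway names. All of its columns of per-library values were used. FPKM divides the fragments of a gene by its length and by the library's total, so a rise in some abundant genes lowers the values of others.

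The deposited FPKM values do not state depth, so it was looked for in the low values. Of 1459 genes with every value under 0.3 FPKM and at least 5 libraries above 0, 99.2% were whole multiples of a common step, within 0.02 of a read, after scaling the libraries. Fragments were thus counted whole, and the steps gave the relative depths. Combining the steps with exon lengths from GENCODE 29 gave a rough depth of 2.99e+07 fragments (median over 1907 genes, quartiles 2.30e+07 and 3.44e+07), which is an estimate since the authors' gene lengths are unknown. At this depth 1 fragment on a transcript of average length is far below 1 FPKM. FPKM is not a count, so no count model was used. Of the 16197 symbols, 15954 matched the RefSeq table directly and 16158 through their Entrez number. Positions are from GENCODE 29 (GRCh38), in which 98.1% of tested genes had one. The positions of SARS1, YARS1, VARS1, H2BC4 and H2BC11 were not matched and are not given.

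Genes with a mean of at least 1 FPKM over the 6 libraries were tested with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with eBayes and a mean-variance trend, two-sided, and Benjamini-Hochberg adjustment. All 6 libraries entered a fit with treatment as the sole term. The threshold was an adjusted p of 0.05, and genes past it with an absolute log2 fold change of at least 1 were also counted. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 3 members were tested, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. With 3 libraries against 3, an exact permutation test of a single gene cannot give a two-sided p under 0.1, so none is given.

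The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 10 largest increases and the 10 largest decreases among genes past the threshold with at least 5 FPKM in the higher group and no overlap between groups, leaving out clones, pseudogenes and read-through names. It also named CAD, DHODH and UMPS, the 4 members with the smallest adjusted p in the direction of each list past the threshold, and up to 2 members past the gene threshold with the largest changes of each other list. It gave 113 genes, of which some, and 1 list, are not reported here. CTPS1, ATF3, DDIT3, CD68 and LUM fall outside it and were chosen after their values were seen.

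Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios, TPM and trimmed-mean scaling, a replicate block, robust variance, protein-coding genes only, and leaving out each library in turn. Tests planned for a table of counts were not run. After seeing the data, 3 further settings were added. One left out BRQ libraries 1 and 2, which leaves 1 BRQ library and a spread from the DMSO libraries alone, and the other 2 removed each library's trend with genomic span, centred on the library's own median or on that of the fitted trend. The centring on the fitted trend was run first, and the library's own median was chosen after that result was seen, because the first form shifted the median log2 fold change of all genes from 0.06 to 0.11. Both are reported. The gene test was tested on simulated data made from the means and residual spreads of the 10689 tested genes, with 200 genes changed by 1.5-fold or 2-fold and a list of others shifted slightly. It recovered 92.0% of genes changed by 1.5-fold and 98.0% of those changed by 2-fold, and 5.63% of its calls were of unchanged genes. The simulated spread was independent between genes, and no difference was shared across a library. Far fewer genes were changed than the 62.1% called in the data. These rates therefore do not cover false calls from differences between whole libraries. The pathways of the table were tested with camera in the same way where at least 10 genes were tested. Figures were drawn with matplotlib 3.10.9.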

Results

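RNA was sequenced from cells labelled Panc1, an established line from a human pancreatic ductal adenocarcinoma, after exposure to the solvent DMSO or to BRQ. The series title names an inhibitor of DHODH, the mitochondrial enzyme that makes orotate in pyrimidine synthesis, and BRQ is read here as brequinar, a known inhibitor of that enzyme. Each group held 3 libraries, for 6 in all. The identity of the cells was not tested, and they expressed CDKN2A (46.3 ± 2.73 FPKM in DMSO), a gene that this line is generally described as lacking. Dose and exposure time were not given in the sources used here. The labels did not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The deposited table listed 16197 genes as FPKM (fragments scaled to transcript length and library total), without counts, and each gene was above 0 in at least 1 library. The steps between low values gave relative depths of 0.977, 0.958 and 0.986 in DMSO libraries 1, 2 and 3 and of 1.02, 1.03 and 1.03 in BRQ libraries 1, 2 and 3, so every BRQ library was deeper than every DMSO library. Below, levels are means ± SD over the 3 libraries of a group (n = 3). Fold changes are BRQ over DMSO on the log2(FPKM + 1) scale with their SE, which understates the change of genes near or under 1 FPKM.

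The libraries separated by treatment. The first principal component carried 83.0% of the variance and split BRQ from DMSO, and the next carried 5.81%. Pearson correlations of log2(FPKM + 1) were 0.995 to 0.997 between libraries of a group and 0.968 to 0.974 between groups. No value of at least 1 FPKM was identical between any pair of libraries. Haemoglobin transcripts set BRQ libraries 1 and 2 apart from the rest. HBB stood at 64.2 and 32.8 FPKM there, against 0.739 FPKM in BRQ library 3 and 0.0488, 0.0498 and 0.677 FPKM in the DMSO libraries.

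The comparison asks how gene expression in Panc1 cells differed after DHODH inhibition. Cells given BRQ had more RNA from genes of DNA replication and the G1/S transition, from cholesterol synthesis, from MHC class I presentation and from the nuclear-encoded respiratory chain. They had less from the listed genes of ribosome biogenesis, ribosomal proteins and tRNA synthetases, although the wider KEGG pathways of the ribosome and of ribosome biogenesis did not pass (camera adjusted p = 0.0962 and 0.167). These lists passed camera at its preset correlation, and none passed with an estimated correlation (lowest adjusted p = 0.283). Among single genes, the histone chaperone ASF1B rose from 15.7 ± 0.378 to 92.3 ± 8.70 FPKM (limma adjusted p = 3.00e-09), and the chemokine CXCL1 fell from 264 ± 5.89 to 103 ± 3.41 FPKM (adjusted p = 1.20e-08). Of 10689 genes with a mean of at least 1 FPKM, 6638 (62.1%) passed a limma adjusted p of 0.05, with 3946 higher and 2692 lower in BRQ. Most changes were small, since 210 genes moved by 2-fold or more, 166 higher and 44 lower. The 3 BRQ values lay apart from the 3 DMSO values in 67.2% of tested genes, where chance gives 10%. The 2-fold count was 402 (288 higher and 114 lower) with a pseudocount of 0.1 and 345 (115 lower) with TPM scaling. The share of higher genes among those changed was 59.4%. It was 51.3% (3392 higher and 3217 lower) with median-of-ratios scaling, 51.5% (3484 and 3283) with TPM scaling and 51.6% (3407 and 3193) with trimmed-mean scaling, and it was 69.9% (4474 higher and 1930 lower) under 1 of 2 centrings of a correction for genomic span, the one run first.

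**Figure D1:**
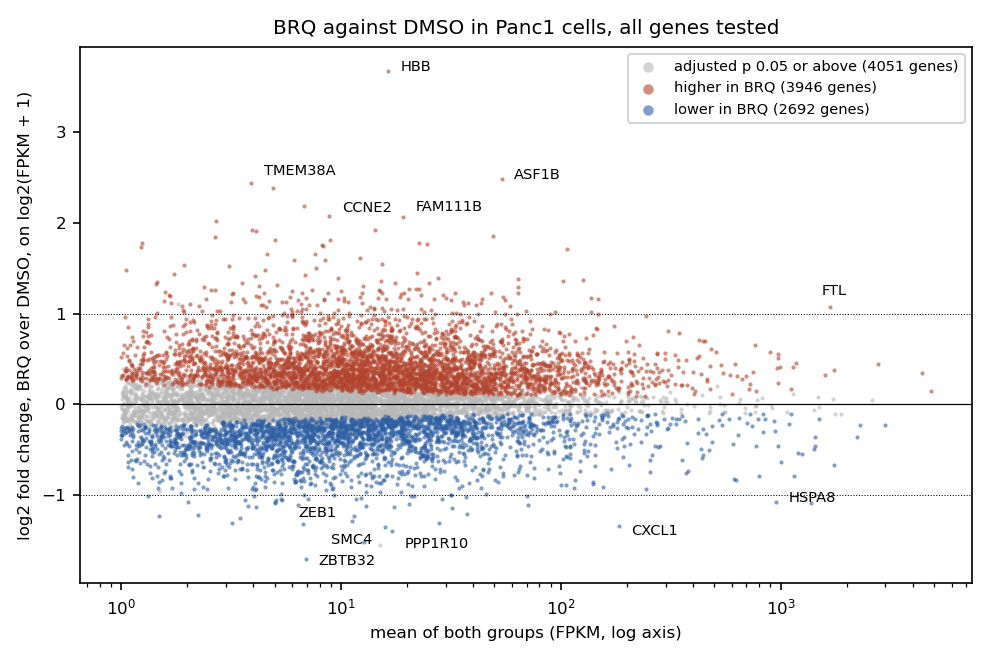
Log2 fold change of BRQ over DMSO on log2(FPKM + 1) against the mean FPKM of both groups on a log axis, with 1 point for each of the 10689 genes tested. Colours mark the 3946 genes higher and the 2692 genes lower at a limma adjusted p of 0.05, and dotted lines mark a 2-fold change; HBB, the topmost point, was high in 2 of the 3 BRQ libraries.

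The genes with the largest increases, by a rule fixed before the data were examined, included ASF1B, the cyclin CCNE2, the protease FAM111B and the coenzyme Q-binding protein COQ10A. ASF1B lies on chromosome 19 from 14119509 to 14136956 (GRCh38), and its log2 fold change was 2.48 ± 0.06. CCNE2, on chromosome 8 from 94879770 to 94896678, rose from 2.79 ± 0.195 to 14.9 ± 0.311 FPKM with a log2 fold change of 2.07 ± 0.07 (adjusted p = 1.56e-08). FAM111B rose from 6.82 ± 0.624 to 31.6 ± 1.26 FPKM and COQ10A from 5.49 ± 1.65 to 23.2 ± 1.28 FPKM. Low in DMSO were TMEM38A, a cation channel of the endoplasmic reticulum (0.531 ± 0.0957 against 7.30 ± 0.480 FPKM in BRQ), VASN, a membrane glycoprotein (0.918 ± 0.409 against 8.94 ± 1.10), RND1 (1.79 ± 0.171 against 11.7 ± 1.17) and CABYR, a calcium-binding protein (1.07 ± 0.356 against 6.78 ± 0.133). Each of these had 3 BRQ values above all 3 DMSO values and an adjusted p of at most 9.02e-07. HBB and HBA1 also met the rule, at 32.6 ± 31.7 and 5.32 ± 5.32 FPKM in BRQ, with log2 fold changes of 3.67 ± 0.99 and 2.02 ± 0.61. Their BRQ means rested on libraries 1 and 2. Without these, 1 BRQ library remained, assumed to vary like the DMSO libraries that alone gave the spread, and the log2 fold changes were 0.50 (adjusted p = 0.129) and 0.10 (adjusted p = 0.614). Over all alternatives the adjusted p ran from 7.25e-07 to 0.129 for HBB and from 4.52e-06 to 0.614 for HBA1, which did not pass without BRQ library 1 (0.0526). HBA1 and its neighbour HBA2 are nearly identical in sequence, so the split of reads between them is uncertain.

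Among the largest decreases were CXCL1, SMC4, a core subunit of the condensin complex, and ZEB1, a transcription factor that represses epithelial genes. CXCL1, on chromosome 4 from 73869393 to 73871242, had a log2 fold change of -1.35 ± 0.04. SMC4, on chromosome 3 from 160399274 to 160434962, fell from 23.2 ± 0.491 to 8.47 ± 0.0838 FPKM (log2 fold change -1.35 ± 0.05, adjusted p = 2.31e-08). ZEB1, on chromosome 10 from 31318495 to 31529814, fell from 16.5 ± 0.683 to 6.14 ± 0.275 FPKM (log2 fold change -1.29 ± 0.06, adjusted p = 8.16e-08). The zinc finger gene ZBTB32 fell from 11.2 ± 0.305 to 2.72 ± 0.251 FPKM, with a log2 fold change of -1.71 ± 0.07. The phosphatase regulator PPP1R10 fell from 25.3 ± 2.71 to 8.91 ± 0.458 FPKM, the beta-arrestin ARRB1 from 40.2 ± 0.896 to 15.5 ± 0.461 and the spindle and kinetochore gene SKA2 from 16.4 ± 0.922 to 6.42 ± 0.182. KIAA1549L fell from 19.5 ± 1.93 to 6.15 ± 0.587 FPKM, the potassium channel KCNQ3 from 5.31 ± 0.290 to 1.64 ± 0.175 and RPL22L1, a paralog of a ribosomal protein, from 10.02 ± 1.48 to 3.41 ± 0.581. The largest adjusted p among these 10 genes was 3.57e-06.

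**Figure D2:**
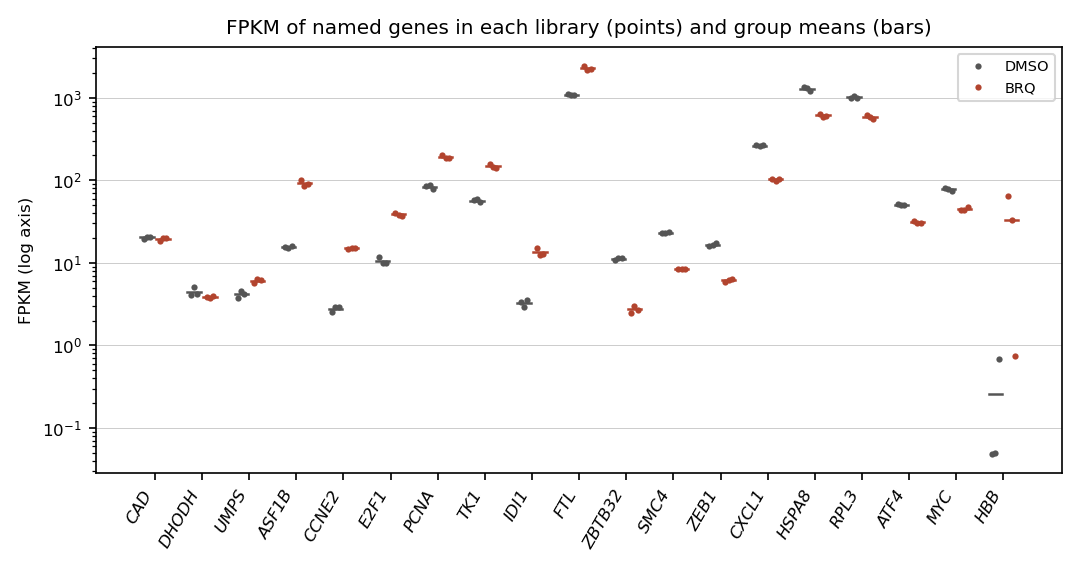
FPKM of named genes on a log axis, with 1 point per library (DMSO grey, BRQ red) and a bar at each group mean. The groups lie apart for the genes shown from UMPS to MYC, overlap for CAD and lie close for DHODH, and HBB is at 64.2 and 32.8 FPKM in BRQ libraries 1 and 2 but at 0.739 in library 3.

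DHODH itself, on chromosome 16 from 72008588 to 72027664, stood at 4.44 ± 0.513 FPKM in DMSO and 3.87 ± 0.123 in BRQ, and the difference did not pass the test (log2 fold change -0.15 ± 0.08, limma adjusted p = 0.123). It passed, at a log2 fold change of -0.24 (adjusted p = 0.0234), when a trend with genomic span was removed and centred on each library's own median, but not with the other centring, and the adjusted p ran from 0.0234 to 0.458 over all alternatives. CAD, whose protein carries out the first steps of pyrimidine synthesis, was at 20.3 ± 0.603 and 19.6 ± 0.959 FPKM (log2 fold change -0.05 ± 0.05, adjusted p = 0.419). UMPS, which makes UMP from orotate, rose from 4.16 ± 0.386 to 6.05 ± 0.371 FPKM (log2 fold change 0.45 ± 0.08, adjusted p = 4.96e-04). As a list, these 3 genes did not stand apart from other genes (camera adjusted p = 0.947). An enzyme inhibitor need not change the RNA of its target, so DHODH RNA is no check of the labels.

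Genes of CTP and deoxynucleotide synthesis rose as a list. Of 12 measured members, 7 rose, 1 fell and 4 did not pass (8 and 1 adjusted over the list alone; camera adjusted p = 0.0318). With an estimated correlation the adjusted p was 0.447, and it ran from 0.00573 to 0.447 over all alternatives with camera. The call was also lost without BRQ libraries 1 and 2 (adjusted p = 0.0661), a fit with 1 BRQ library whose spread came from the DMSO libraries alone. The wider KEGG pathway of pyrimidine metabolism did not pass, with 12 of 43 genes higher and 9 lower (camera adjusted p = 0.992). The ribonucleotide reductase subunits RRM1 (22.8 ± 0.833 to 36.9 ± 0.432 FPKM) and RRM2 (60.6 ± 2.23 to 86.1 ± 0.799) and thymidylate synthase TYMS (48.01 ± 2.02 to 72.2 ± 4.36) rose. CTPS1, a CTP synthase, was at a log2 fold change of 0.07 (adjusted p = 0.278). Pyrimidine salvage and transport genes did not move as a list (6 of 15 rose and 3 fell, also over the list alone; camera adjusted p = 0.722). Within it, thymidine kinase TK1 rose from 56.8 ± 2.09 to 147 ± 9.45 FPKM (adjusted p = 2.76e-08) and the nucleoside transporter SLC29A2 fell from 8.42 ± 0.543 to 4.61 ± 0.506 FPKM. Of the 5 measured genes of pyrimidine breakdown, 4 fell and none rose (also over the list alone; camera adjusted p = 0.00772, and adjusted p = 0.420 with an estimated correlation). They were the nucleotidases NT5C3A (56.95 ± 3.06 to 29.5 ± 2.20 FPKM) and NT5E (66.2 ± 0.282 to 43.02 ± 1.66), thymidine phosphorylase TYMP (80.6 ± 2.04 to 65.1 ± 1.21) and dihydropyrimidine dehydrogenase DPYD (3.98 ± 0.374 to 1.87 ± 0.221). DPYD spans a long stretch of chromosome 1, from 97077743 to 97995000, and its call ended when a trend with genomic span was removed (log2 fold change -0.18, adjusted p = 0.129; 1.27e-05 to 0.286 over all alternatives). In purine synthesis, 3 of 13 genes rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.180), among them PRPS1, up from 25.7 ± 0.464 to 41.7 ± 1.43 FPKM, and ADSL, down from 19.1 ± 0.908 to 12.4 ± 0.349. Of 19 UDP-sugar and hexosamine genes, 10 rose and 5 fell (also over the list alone; camera adjusted p = 0.669), with GALT up from 10.3 ± 1.16 to 16.5 ± 0.390 FPKM and EXT1 down from 23.7 ± 0.0680 to 14.5 ± 0.571.

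DNA replication and G1/S genes gave the lowest camera p of the lists. Of 44 members, 36 rose, 1 fell and 7 did not pass (37 and 1 adjusted over the list alone), with a median log2 fold change of 0.63 and a camera adjusted p of 6.65e-09 (adjusted p = 0.283 with an estimated correlation). CCNE1, the other cyclin E, rose from 11.4 ± 0.427 to 32.8 ± 1.13 FPKM, the transcription factor E2F1 from 10.6 ± 1.13 to 38.5 ± 1.32 and the polymerase clamp PCNA from 84.03 ± 4.85 to 191 ± 8.10, each with an adjusted p of at most 5.33e-08. Genes of G2 and mitosis moved both ways, with 17 of 40 higher and 12 lower (also over the list alone; camera adjusted p = 0.895). Of these, the kinase PLK1 fell from 49.9 ± 1.60 to 26.8 ± 1.73 FPKM and the spindle gene ASPM from 11.2 ± 0.283 to 5.75 ± 0.358. Of 25 genes of replication stress and DNA repair, 13 rose and 3 fell (also over the list alone; camera adjusted p = 0.213), with RMI2 up from 7.05 ± 0.484 to 17.9 ± 1.11 FPKM and RAD51AP1 from 6.57 ± 0.578 to 12.2 ± 1.53. Of 18 replication-dependent histone genes measured, 7 rose and 2 fell (also over the list alone; camera adjusted p = 0.439), with H2BC4 up from 6.09 ± 0.282 to 11.4 ± 0.349 FPKM and H2BC11 down from 3.96 ± 0.576 to 2.13 ± 0.561. Histone genes have close copies, so reads may have been split between them.

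Cholesterol genes rose together, 20 of 22 higher and none lower (also over the list alone; camera adjusted p = 3.19e-06; adjusted p = 0.283 with an estimated correlation). The isopentenyl isomerase IDI1 went from 3.27 ± 0.292 to 13.4 ± 1.39 FPKM, the reductase DHCR7 from 22.8 ± 1.38 to 49.7 ± 2.97 and the sterol sensor INSIG1 from 8.72 ± 0.677 to 20.8 ± 1.08. The largest adjusted p of these 3 genes was 2.45e-07. Fatty acid synthesis genes split, with 5 of 10 higher and 4 lower (also over the list alone; camera adjusted p = 0.884). The desaturase SCD rose from 40.4 ± 1.45 to 72.4 ± 2.49 FPKM and ACSS2, which makes acetyl-CoA from acetate, from 19.01 ± 0.613 to 34.6 ± 1.79.

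Genes of MHC class I presentation rose in 15 of 17 cases, and 1 fell (also over the list alone; camera adjusted p = 8.86e-05; adjusted p = 0.304 with an estimated correlation). HLA-B rose from 346 ± 20.9 to 563 ± 4.36 FPKM, the peptide-loading factor TAPBP from 80.02 ± 1.57 to 137 ± 4.17 and the transcription factor IRF1 from 39.5 ± 1.34 to 71.7 ± 0.809. HLA genes resemble each other, and their values are uncertain where reads were split between them. Interferon-stimulated genes did not move one way, with 16 of 38 higher and 14 lower (17 and 14 adjusted over the list alone; camera adjusted p = 0.895). GBP1 rose from 33.1 ± 2.42 to 67.9 ± 1.58 FPKM, and the interferon gene IFNL1 fell from 49.5 ± 3.05 to 29.7 ± 3.84. Of 20 NF-kB and inflammatory genes, 6 rose and 8 fell (also over the list alone; camera adjusted p = 0.282). The chemokine CXCL2 fell with CXCL1, from 52.9 ± 1.87 to 22.3 ± 0.859 FPKM (adjusted p = 3.53e-08). Of 16 immediate-early genes, 5 rose and 10 fell (also over the list alone; camera adjusted p = 0.153; 0.0207 in genes of at least 5 FPKM, 0.0207 and 0.00746 under the 2 span corrections and 0.00746 to 0.447 over all alternatives with camera), with KLF2 down from 8.30 ± 0.704 to 4.11 ± 0.0685 FPKM and MYC from 77.9 ± 2.81 to 44.9 ± 1.81.

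Nuclear genes of the respiratory chain rose in 31 of 38 cases and fell in 1 (32 and 1 adjusted over the list alone; camera adjusted p = 1.24e-04; adjusted p = 0.569 with an estimated correlation). The complex I genes NDUFA2, NDUFB10 and NDUFA1 rose from 42.1 ± 2.10 to 66.9 ± 2.67, from 229 ± 10.04 to 310.4 ± 4.36 and from 90.6 ± 4.10 to 127 ± 4.68 FPKM, and UQCRQ of complex III from 40.3 ± 1.61 to 66.1 ± 4.90. None of the 13 genes of the mitochondrial genome was in the table, so that list was not tested. Of 11 ubiquinone synthesis genes, 3 rose and 3 fell (also over the list alone; camera adjusted p = 0.895), with COQ6 up from 4.20 ± 0.664 to 9.70 ± 0.292 FPKM and COQ9 from 30.7 ± 1.70 to 52.4 ± 1.48. Of 20 ferroptosis and antioxidant genes, 11 rose and 4 fell (also over the list alone; camera adjusted p = 0.138). The ferritin light chain FTL rose from 1081 ± 17.3 to 2269.6 ± 118 FPKM (adjusted p = 5.16e-08).

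Lysosome and autophagy genes rose in 20 of 24 cases and fell in 1 (also over the list alone; camera adjusted p = 0.00267; adjusted p = 0.447 with an estimated correlation). MCOLN1, a lysosomal calcium channel, rose from 11.8 ± 0.506 to 20.7 ± 1.88 FPKM, MAP1LC3B from 62.7 ± 2.61 to 92.4 ± 2.99, LAMP1 from 114 ± 1.76 to 151 ± 2.27 and CTSA from 109 ± 4.003 to 146 ± 1.30. Of the KEGG pathways, that of the lysosome passed as higher (69 of 109 genes higher and 13 lower, camera adjusted p = 0.00271; adjusted p = 0.573 with an estimated correlation), and the pathways of autophagy did not pass (45 of 119 higher and 32 lower, adjusted p = 0.908, and 12 of 30 higher and 7 lower, adjusted p = 0.766). Of 27 genes of glycolysis and hypoxia, 17 rose and 5 fell (also over the list alone; camera adjusted p = 0.0387; adjusted p = 0.304 with an estimated correlation). The peptide hormone gene ADM rose from 9.55 ± 0.686 to 22.6 ± 1.07 FPKM, ANKRD37 from 3.12 ± 0.375 to 8.81 ± 0.325, the collagen hydroxylase P4HA1 from 23.2 ± 0.833 to 42.9 ± 2.19 and the glycolytic enzyme TPI1 from 324 ± 8.65 to 528 ± 22.6. The KEGG pathway of glycolysis and gluconeogenesis passed as higher (27 of 44 genes higher and 5 lower, camera adjusted p = 0.0234; adjusted p = 0.581 with an estimated correlation), and that of HIF-1 signaling did not pass (28 of 76 higher and 23 lower, adjusted p = 0.776). The call of the fixed list of glycolysis and hypoxia ended in genes of at least 5 FPKM (adjusted p = 0.123) and without DMSO library 2 or BRQ library 2 (adjusted p = 0.0505 and 0.0507; 0.00842 to 0.304 over all alternatives with camera).

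Ribosomal protein genes fell in 22 of 45 cases and rose in 3 (also over the list alone; camera adjusted p = 8.86e-05; adjusted p = 0.673 with an estimated correlation). The median log2 fold change of this list was -0.11. The KEGG pathway of the ribosome, which also holds mitochondrial ribosomal proteins, did not pass, with 44 of 126 genes lower and 31 higher (camera adjusted p = 0.0962). RPL3 fell from 1013 ± 23.2 to 583 ± 30.2 FPKM, RPL4 from 468 ± 9.24 to 276 ± 14.4, RPL7A from 1487 ± 34.4 to 1016 ± 49.5 and RPL5 from 533 ± 15.4 to 359.8 ± 23.2. Ribosomal protein genes have many processed pseudogenes, so reads may have been shared. Ribosome biogenesis and RNA polymerase I genes fell in 28 of 44 cases and rose in 7 (30 and 8 adjusted over the list alone; camera adjusted p = 1.82e-04; adjusted p = 0.304 with an estimated correlation). The KEGG pathway of ribosome biogenesis did not pass, with 26 of 70 genes lower and 17 higher (adjusted p = 0.167), nor did that of RNA polymerases, with 6 of 31 lower and 17 higher (adjusted p = 0.428). In the fixed list, MYC had an adjusted p of 3.19e-07, the polymerase I factor TAF1D fell from 39.4 ± 2.28 to 18.6 ± 1.63 FPKM, the nucleolar protein NPM1 from 471 ± 9.08 to 284 ± 17.6 and the helicase DDX21 from 68.7 ± 1.94 to 49.3 ± 1.28.

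**Figure D3:**
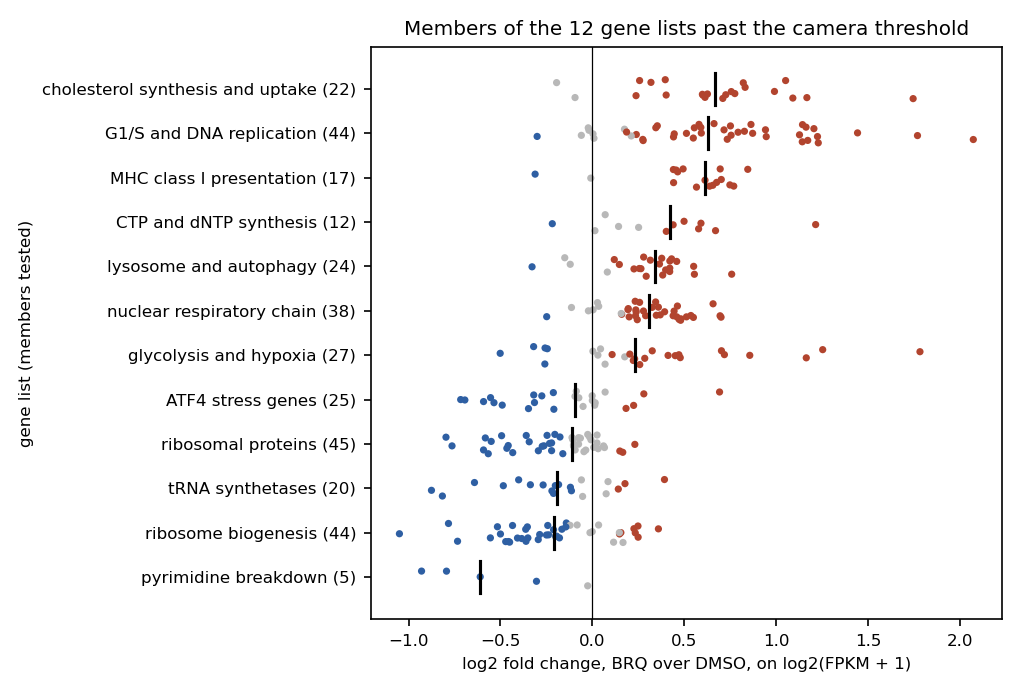
Log2 fold change of BRQ over DMSO on log2(FPKM + 1) for each tested member (points) of the 12 lists past the camera threshold, with a bar at the list median and colours for a limma adjusted p under 0.05 (red higher, blue lower, grey not passed). Of the 44 replication genes 36 lie to the right in red, and of the 44 ribosome biogenesis genes 28 lie to the left in blue.

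The tRNA synthetases fell in 13 of 20 cases and rose in 3 (also over the list alone; camera adjusted p = 0.00667; adjusted p = 0.304 with an estimated correlation). SARS1 fell from 96.5 ± 2.98 to 54.4 ± 2.35 FPKM, YARS1 from 88.6 ± 2.75 to 56.4 ± 1.14, VARS1 from 51.7 ± 1.44 to 36.6 ± 0.807 and FARSB from 7.32 ± 0.674 to 3.53 ± 0.0695. Genes of the ATF4 stress response fell in 12 of 25 cases and rose in 4 (also over the list alone; camera adjusted p = 0.0147; adjusted p = 0.304 with an estimated correlation). ATF4 fell from 50.6 ± 1.23 to 30.9 ± 1.06 FPKM, the mitochondrial folate enzyme MTHFD2 from 55.3 ± 1.02 to 33.3 ± 0.592, DDIT4 from 133 ± 2.63 to 87.9 ± 3.51 and the amino acid transporter SLC7A1 from 34.6 ± 1.26 to 24.4 ± 1.58. ATF3 and DDIT3, in the same list, rose by log2 fold changes of 0.69 and 0.28. Of 19 genes of the unfolded protein response, 4 rose and 11 fell (also over the list alone; camera adjusted p = 0.110), with HERPUD1 down from 22.8 ± 0.744 to 14.97 ± 0.832 FPKM and ERN1 from 4.34 ± 0.416 to 2.65 ± 0.264. Of 12 heat shock genes, 2 rose and 6 fell (also over the list alone; camera adjusted p = 0.0823; 0.0494 without DMSO library 3, 0.0302 without BRQ library 1 and 0.00216 to 0.679 over all alternatives with camera). The chaperone HSPA8 fell from 1295 ± 72.2 to 612 ± 22.1 FPKM (adjusted p = 6.79e-08), and its partner DNAJA1 rose from 177 ± 2.99 to 278 ± 17.8.

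Of 18 BCL2-family and caspase genes, 6 rose and 8 fell (also over the list alone; camera adjusted p = 0.408), with PMAIP1 down from 109 ± 3.88 to 66.04 ± 6.68 FPKM. Of 12 senescence and CDK inhibitor genes, 6 rose and 3 fell (also over the list alone; camera adjusted p = 0.720), with IGFBP3 up from 88.1 ± 4.61 to 129 ± 1.67 FPKM. Of 24 genes of transcription elongation, 10 rose and 7 fell (also over the list alone; camera adjusted p = 0.895). MEPCE and HEXIM1, parts of the complex that holds the elongation kinase P-TEFb inactive, rose from 32.9 ± 0.705 to 75.97 ± 0.720 and from 14.3 ± 1.33 to 27.5 ± 0.0729 FPKM.

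Of 16 mesenchymal genes, 5 rose and 7 fell (also over the list alone; camera adjusted p = 0.185), and their regulators moved apart. SNAI1 rose from 0.607 ± 0.221 to 4.73 ± 0.425 FPKM (log2 fold change 1.84 ± 0.11, adjusted p = 3.30e-07), while ZEB1 fell. Of 15 epithelial genes, 4 rose and 6 fell (also over the list alone; camera adjusted p = 0.722), with the mucin MUC1 up from 35.2 ± 1.89 to 62.7 ± 3.94 FPKM and TJP3 down from 6.68 ± 0.279 to 4.32 ± 0.434. Of 9 classical-subtype pancreatic cancer genes, 4 rose and 1 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.895). CEACAM6 went from 5.48 ± 0.429 to 7.18 ± 0.832 FPKM and AGR2 from 8.06 ± 1.01 to 10.2 ± 1.49, with an adjusted p of 0.0246. The AGR2 call was lost under each of the 3 other scalings (0.0512 to 0.0528), without a filter and without DMSO library 2, DMSO library 3 or BRQ library 3 (0.0718, 0.0882 and 0.102; 0.00643 to 0.102 over all alternatives). Of 14 basal-like genes, 4 rose and 4 fell (also over the list alone; camera adjusted p = 0.720), with the growth factor AREG up from 45.3 ± 4.31 to 93.1 ± 4.75 FPKM and TNS4 down from 2.55 ± 0.117 to 1.31 ± 0.226. Of 5 genes of pancreatic lineage, none rose and 3 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.182), among them HES1, from 10.1 ± 0.673 to 5.45 ± 0.690 FPKM, and HNF4A, from 17.2 ± 0.644 to 13.99 ± 0.391.

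Few markers of other cell types reached a mean of 1 FPKM. Of 4 leukocyte and blood markers tested, 3 rose and none fell (also over the list alone; camera adjusted p = 0.397). They were HBB and HBA1, whose values were high in BRQ libraries 1 and 2 alone, and CD68, while FCER1G did not pass; CD68 went from 107 ± 3.09 to 158 ± 4.89 FPKM. The fibroblast list had 1 gene at 1 FPKM or more, LUM, which went from 52.5 ± 0.898 to 78.6 ± 2.55 FPKM. No endothelial, acinar or endocrine marker reached a mean of 1 FPKM. In all, 37 lists were tested and 12 passed camera at its preset correlation of 0.01, 7 higher and 5 lower. With an estimated correlation camera passed 0, with 3 at an unadjusted p under 0.05, and the lowest adjusted p was 0.283. By fry, which tests only whether a list's genes move one way on balance, 31 passed. Median, mean and camera direction differed in sign for the pyrimidine synthesis, interferon, G2 and mitosis, ubiquinone, epithelial and basal-like lists.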

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

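The alternatives that removed the span trend or left out BRQ libraries 1 and 2 were chosen only after the data were seen. The count of changed genes stayed within 1.5 times 6638 under every setting tried, from 5152 in genes of at least 5 FPKM to 6799 with the replicate block. It was 6037 to 6404 without any single library and 5203 without BRQ libraries 1 and 2. That fit had 1 BRQ library, assumed to vary like the 3 DMSO libraries that alone gave its spread, so it says little of stability. None of the 6638 was called with the other sign, except for 27 and 48 under the 2 centrings of the span correction. The genes behind the counts did change. Of the 6638, 539 to 588 were not called or not tested under the 3 other scalings. The same held for 1365 with the span trend removed and centred on each library's own median, and for 1187 with the other centring. The 2-fold count of 210 rose to 402 (288 higher, 114 lower) with a pseudocount of 0.1, and to 345 (115 lower) with TPM scaling, which raises the values against the pseudocount and also tested more genes (11646); which of these raised the count was not tested. The lists past the threshold went from 12 to 0 with an estimated correlation (0 higher, 0 lower), with 3 at an unadjusted p under 0.05. Among those 12 lists the estimate ran from 0.00215 for glycolysis and hypoxia to 0.770 for ribosomal proteins. For glycolysis and hypoxia and for ATF4 stress genes (0.00247) it lay under the preset 0.01. The unadjusted camera p still rose, from 0.0126 to 0.0526 for glycolysis and hypoxia and from 0.00399 to 0.0357 for ATF4 stress genes. Members that move together thus do not explain the loss of these lists. A list that failed with an estimated correlation is therefore not by that alone shown to hold members that move together. With fry, which does not compare a list with other genes, the lists past the threshold went to 31 (18 higher, 13 lower). With the span trend removed and centred on the fitted trend, 8 lists passed as lower. DHODH passed with the span trend removed (-0.24). The cause of these span results was not tested. Alternatives planned for a table of counts were not run, since the values are FPKM. Median-of-ratios scaling left 51.3% of changed genes higher, against 59.4% as deposited.

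The numbers 1, 2 and 3 were not taken to pair the libraries. Correlations of same-numbered libraries after removing group means were 0.144, 0.00804 and 0.0584, and 4 of 6 libraries matched best the library of their own number. With the replicate block, 6799 genes and 11 lists passed, and the glycolysis and hypoxia list did not (adjusted p = 0.0506; 0.00842 to 0.304 over all alternatives with camera).

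No list that passed changed direction. The lists that turned were all ones that had not passed: without a filter, G2 and mitosis (adjusted p = 0.922) and the leukocyte markers (0.467); in genes of at least 5 FPKM, ubiquinone (0.740) and classical-subtype genes (0.936). With fry they were pyrimidine synthesis (0.299), interferon (0.0885), G2 and mitosis (0.415), ubiquinone (0.0140), epithelial (0.126) and basal-like genes (0.764). Fry compares a list with no change and camera with the other genes, so their directions can differ. The median log2 fold change of all tested genes was 0.06. Without single libraries, interferon turned without DMSO library 1 (range without any 1 library 0.887 to 0.997), pyrimidine synthesis without DMSO library 2 or BRQ library 1 (0.901 to 0.961) and ubiquinone without BRQ library 3 (0.811 to 0.989). Without BRQ libraries 1 and 2 they were pyrimidine synthesis (0.876) and interferon (0.944). With the span trend removed pyrimidine salvage turned (0.948), as it did with the other centring (0.940), where the senescence list also turned (0.940). The cause of the turns other than those with fry was not tested. Lists not past the threshold gained a call in 33 cases, most of them by fry. Among others, and apart from fry, immediate-early genes gained it in genes of at least 5 FPKM and under both span corrections (0.0207, 0.0207 and 0.00746), heat shock without a filter and under both span corrections (0.0459, 0.00366 and 0.00216), the unfolded protein response under both (0.0151 and 0.0146), NF-kB genes under the one centred on the fitted trend (0.0454) and ferroptosis genes without a filter (0.0269). Lists past the threshold lost theirs in 17, of which 12 were with an estimated correlation. No named gene changed sign in any setting. Across settings 14 values of single genes lost their call, all of HBB, HBA1, AGR2 and DPYD, and 1 gained it. Depth limits genes near 1 FPKM most, where the pseudocount shrinks a fold change.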

Other observations

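Pathways named in the deposited table gave groups that the lists above do not cover. Of 304 KEGG pathways with at least 10 tested genes, 47 passed limma's camera at the preset correlation, 31 higher and 16 lower, and 0 passed with an estimated correlation (16 at an unadjusted p under 0.05, lowest adjusted p = 0.573). The pathways below were picked from these results. Of 26 genes of xenobiotic metabolism by cytochrome P450 20 were higher and 1 lower (camera adjusted p = 0.00271), and of 38 of glutathione metabolism 26 were higher and 2 lower (0.00271), while the related pathways of drug metabolism by cytochrome P450 (0.0518) and by other enzymes (0.399) did not pass. The epoxide hydrolase EPHX1 rose from 36.7 to 91.7 FPKM, AKR7A2 from 9.55 to 21.1 and the glutathione peroxidase GPX1 from 104 to 187. In peroxisomes 39 of 64 genes rose and 7 fell (0.0126), among them EPHX2, from 3.17 to 12.1 FPKM, and PHYH, a phytanic acid oxidase, from 7.41 to 23.5. Genes of valine, leucine and isoleucine breakdown rose in 26 of 38 cases and fell in 2 (0.00422). On the log2(FPKM + 1) scale the 5 genes named rose by 1.30 ± 0.05, 1.07 ± 0.06, 0.84 ± 0.05, 1.65 ± 0.08 and 1.55 ± 0.09 (SE, 3 libraries per group, largest limma adjusted p = 2.89e-07), in the order given. They were chosen after their values were seen.

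Some pathways of cell contact passed as lower at the preset correlation, and none did with an estimated one (adjusted p = 0.625 for adherens junctions, 0.606 for focal adhesion and 0.573 for Wnt). Of 62 adherens junction genes 33 were lower and 11 higher (camera adjusted p = 0.00309), and of 123 focal adhesion genes 56 were lower and 28 higher (0.00459). The trend with genomic span was not removed from any of the pathway tests, so its share in these results is unknown. Tight junction (39 of 113 lower, 33 higher, 0.256), ECM-receptor interaction (16 of 35 lower, 10 higher, 0.166) and cell adhesion molecules (10 of 47 lower, 19 higher, 0.650) did not pass. The cytoplasmic actins ACTB and ACTG1 fell from 2163 to 1354 and from 1464 to 843 FPKM. In the Wnt pathway 45 of 95 genes fell and 20 rose (0.00459), with DKK1, a secreted Wnt inhibitor, down from 60.8 to 30.2 FPKM and DVL1 from 89.0 to 51.3. The large subunit of RNA polymerase II, POLR2A, rose from 49.4 ± 2.91 to 164 ± 11.7 FPKM (SD, n = 3; limma adjusted p = 1.89e-08) and the mRNA export factor NXF1 from 20.6 ± 0.332 to 77.4 ± 2.82 (adjusted p = 3.00e-09). The log2 fold changes of ACTB, ACTG1, DKK1 and DVL1 were -0.68 ± 0.04, -0.80 ± 0.04, -0.99 ± 0.07 and -0.78 ± 0.04 (SE; largest limma adjusted p = 1.13e-06). These genes were also chosen after their values were seen.

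In the next paragraphs, the test of haemoglobin ratios and the comparison of library pairs were chosen only after the results were seen. Genes with a long genomic span were lower in BRQ: of 1761 genes over 100 kb, 52.4% fell and 11.1% rose, and of 2072 genes under 10 kb, 18.5% fell and 50.05% rose. Across 10481 genes, which are not independent replicates, Spearman's rho of log2 fold change with span was -0.332, and it was -0.349 to -0.300 without single libraries. Exon length, the union of a gene's annotated exons, had a rho of -0.270 with log2 fold change. Given exon length and mean FPKM, the partial rho with span was -0.212. Such a length is not that of the transcripts the cells made, so transcript length as a cause was not settled. The tables argue against GC content as the whole cause (partial rho -0.313 given GC content and mean FPKM). They also argue against low expression (-0.304 in genes of at least 10 FPKM). The median log2 fold change dropped from short to long genes in each of 3 levels of expression (smallest drop -0.33), but any cause that follows span gives this, so it does not single out limited transcription of long genes under BRQ. Libraries of a group also differed along span (by up to 0.15, BRQ library 1 against BRQ library 3). The smallest drop between a BRQ and a DMSO library was 1.95 times that. By Spearman's rho the pairs overlapped in size. It reached 0.311 within a group, for BRQ library 1 against BRQ library 3, and was -0.255 in the weakest pair of a BRQ and a DMSO library. Limited transcription of genes with a long span and differences between libraries unrelated to treatment therefore cannot be told apart.

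Genes with a snoRNA on the same strand inside their genomic span, a further group chosen for this part and called hosts here, were also lower. Whether the snoRNA lay in an intron was not checked. Of 179 hosts 74 fell and 30 rose, with a median log2 fold change of -0.12 against 0.04 in lists matched on span, exon length and mean FPKM. The hosts' median lay at percentile 0 of 10000 such lists, so lists of like span, length and level did not reproduce it. These lists draw genes as if independent, and members that move together can make a percentile too extreme. The hosts were not compared between libraries of a group. Without the genes of the fixed ribosomal protein and ribosome biogenesis lists and others with an RPL or RPS symbol, 145 hosts remained. They lay at percentile 0.12, so the lower median was not confined to the genes left out. The same limits hold for this percentile. Ribosome biogenesis genes outside the fixed list may remain among these hosts. Among ribosomal proteins, 27 hosts and 49 other genes differed by -0.07 in median (two-sided permutation p = 0.0865), and why hosts might be lower under BRQ stays untested.

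Haemoglobin RNA in BRQ libraries 1 and 2 may come from blood, as RNA or as reads from another sample. The ratio of HBB to HBA1 plus HBA2 was 2.64 and 2.53 in these libraries, a quotient of 1.04, against 0.667 in BRQ library 3. The erythroid gene ALAS2 stood at 0.230 and 0.199 FPKM there and at no more than 0.0148 FPKM in the others. HBB reached 64.2 FPKM, HBA2 13.6 and HBA1 10.8, while the other erythroid genes listed, such as AHSP and SLC4A1 (at most 0.111 and 0.0116 FPKM), stayed far lower. No biological explanation was tested, since the design does not set BRQ library 3 apart.

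The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split called 6638 genes and the highest of the others called 1, and 1 of 10 splits, the real one, reached 6638. Every other split put libraries of both treatments in each group. The treatment difference then entered the spread, so few calls were bound to follow and the contrast does not measure chance.

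Some levels stood out in cells given DMSO. CDKN2A, a gene that PANC-1 cells are generally described as lacking, was at 46.3 ± 2.73 FPKM in DMSO and 32.5 ± 2.13 in BRQ (SD, n = 3), its neighbour CDKN2B at 15.001 ± 0.575 and 19.7 ± 0.694, and MTAP at 9.80 ± 0.551 and 9.56 ± 0.189. The identity of the cells was not tested here, and this doubt bears on every value given for the line. Some interferon-stimulated genes, picked here for their high values, were abundant without BRQ, with ISG15 at 2480.3 ± 53.4 FPKM, rank 6 of all genes, OASL at 924 ± 14.8 and IFIT3 at 324 ± 7.39, while others of the list were far lower, such as MX1 at 4.44 ± 0.0566 and IFIT5 at 10.8 ± 0.560. In BRQ, ISG15, OASL and IFIT3 were lower, at 2114 ± 97.4, 748 ± 12.7 and 233 ± 4.21 FPKM (largest limma adjusted p = 0.00108). Of the 38 genes of the list, 16 were higher and 14 lower in BRQ.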
